A study of Mus musculus with 3 samples.

How the data were processed

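Gene expression was measured in 3 RNA samples of mouse primary cerebral cultures, 1 each treated with valproate, DMSO or lamotrigine. Per the labels, RNA was extracted with TRIzol, labelled with the single dye Cy3 by the Low Input Quick Amp method and hybridised to an Agilent mouse array. Per the file headers, the intensity of each spot was read with Feature Extraction version 10.7.1.1, and the probes, most of them 60 nt long, were annotated on the mm9 genome build. The 3 arrays were on 1 slide. Per the file headers, the processed signal is the spot intensity after background subtraction and detrending within an array, with no normalization between arrays. Each array had 62976 spots, of which 59305 were not controls, for 55681 probes.

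The authors also deposited a table of intensity values with 1 column per array and 3 columns of presence calls. From the values, the scale was linear and the sorted columns were equal to within 0.0312%, which is the result of a quantile normalization. All 3 columns had a median of 22.6 and a 75th percentile of 353. Each column had a Spearman correlation across probes of at least 0.999 with the processed signal of the array of its own title and of at most 0.952 with another array. The software and settings behind this table and its presence calls were not given in the sources used here. The deposited table served as an alternative source of values, and its presence calls were not used here.

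Levels were computed from the processed signal of the scanner files as log2 minus the log2 of the 75th percentile of the non-control spots of that array. They are printed as scaled signal, in which 100 is the 75th percentile. Spots marked as outliers were left out, which removed 1 probe, and spots of 1 probe were averaged on the log2 scale. A probe was detected on an array if most of its spots were marked as well above background. Probes were joined to genes with a table of RefSeq accessions and symbols. Of the 55681 probes, 27235 were joined by accession, 3581 by symbol and 565 by an older symbol, and 24300 stayed without a gene, 16194 of them probes for long intergenic RNA regions. Each of the 22328 genes was represented by its probe with the highest mean level over the 3 arrays, and 7028 genes had several probes.

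A log2 difference was computed for genes detected on both arrays of a comparison. Where a gene was detected on 1 of them only, the other array was set to its detection floor, a scaled signal of 3.90 for valproate, 5.30 for DMSO and 4.64 for lamotrigine, or to the gene's own signal there where that was higher, and the difference is a lower bound. It was set to 0 where the undetected side then lay at or above the detected one. With 1 array per treatment no test between treatments was possible. Genes at least 2-fold apart were counted as a description of these arrays. For 36 gene lists (26 of pathways, drug targets and reference genes, and 10 of cell type markers), the median log2 difference of the measured members, with bounds included, was ranked among the medians of 10000 random lists of the same size. The random lists were matched on level in 20 bins, and a list was called outside the random range below percentile 2.5 or above percentile 97.5. Technical spread came from 399 probes printed 10 times on each array.

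The levels, thresholds, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule named the 12 highest and 12 lowest genes of valproate against DMSO, the 8 and 8 of lamotrigine against DMSO and the 5 and 5 of valproate against lamotrigine. It left out symbols of clones and predicted genes and named only genes at least 2-fold apart and detected on both arrays. It added the 3 highest bounds in each direction of valproate against DMSO, the class I histone deacetylases, the reference genes and up to 4 members of each list farthest from 0. Other list members that the text names were chosen after their values were seen. Some genes that the rule named are counted in their lists and not reported singly here.

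The counts of genes, the correlation, the list medians and the named genes were recomputed, where they apply, under quantile normalization, centring on the median of detected probes, normexp background correction with an offset of 50, the authors' deposited table, detection on all 3 arrays, no detection filter, the mean of detected probes, outlier spots kept, thresholds of 1.5-fold and 3-fold, 5 bins of level, and the lamotrigine array as the control of valproate. Scaling on the spike-in controls was added after the data were seen. It set the median of 6 spike-in probes with a signal over 100, of 10 on the array, equal between arrays. The sources used here do not say how much spike-in RNA was added to each sample. A list of 42 motile cilium genes was also added after the data were seen. That list, the second probes, the probes without a gene and the overlap between the drugs were computed under the main settings only.

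The procedure was tested on simulated data for 14506 genes. It recovered 96 of 96 genes planted at a log2 difference of 1.5 and 104 of 104 at 2, with 0 unchanged genes at least 2-fold apart. Both planted values lay above the 2-fold threshold, so this run checks the calculation and gives no rate of false calls on the real arrays. Differences there had an SD of 0.42 for valproate and 0.21 for lamotrigine against DMSO. A list of 27 genes moved by 0.3 lay at percentile 100, and 12 of 200 random lists lay outside the central 95%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.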

Results

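Primary cells from the cerebrum of C57BL6/J mouse embryos at embryonic day 18 were grown in neurobasal medium with B27, a serum-free medium for neurons, and were treated for 24 h from day 10 in vitro. The treatments were 1 mM valproate, 100 µM lamotrigine and 0.1% DMSO, the solvent present in every culture. Valproate is an antiepileptic and mood-stabilising drug that inhibits class I histone deacetylases (HDACs), enzymes that remove acetyl groups from histones. Lamotrigine is an antiepileptic drug that blocks voltage-gated sodium channels. There were 3 arrays, 1 per treatment, so none of the differences has a replicate check, no p-value is given, and the number of arrays limits the precision.

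The 75th percentile of signal was 478 on the valproate array, 372 on the DMSO array and 388 on the lamotrigine array. Spots well above background made up 52.9%, 49.6% and 51.6% of the non-control spots, and 15095, 14506 and 14821 of 22328 genes were detected. No spot was saturated (0 on each array). Spots of the same probe had a median SD of 0.06 log2, or 0.09 for a difference of 2 arrays. This technical SD ranged from 0.17 to 0.18 at a scaled signal under 25 and from 0.04 to 0.05 over 400. It covers printing, hybridisation and scanning, and leaves out differences between cultures, RNA extractions and labelling reactions.

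Valproate was set against DMSO to find genes that respond to class I HDAC inhibition in neurons, the purpose of the study. The valproate culture had higher levels of interferon-stimulated genes (median log2 difference 0.76), of genes described as raised by HDAC inhibitors (0.72) and of proliferation genes (0.46). It had lower levels of cholesterol synthesis genes (median -0.63), astrocyte markers (-0.52) and oligodendrocyte lineage markers (-0.38). H2-Ab1, a chain of the class II antigen-presenting molecule, had the highest log2 difference (3.46) among genes detected on both arrays, and Gpr17, a receptor of maturing oligodendrocyte precursors, was 13.5-fold lower. Of 14346 genes detected on both arrays, 302 were at least 2-fold higher and 203 at least 2-fold lower with valproate, 505 in all.

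H2-Ab1 (probe at chromosome 17, 34406296 to 34406355 on mm9) had a scaled signal of 512 with valproate and 46.5 with DMSO. Its other probe gave a log2 difference of 3.29. Tcfl5, a basic helix-loop-helix transcription factor (probe at chromosome 2, 180357383 to 180369981), was 3.43 higher, from 9.97 with DMSO. H2-M3, a class I-like antigen-presenting molecule, was 2.81 higher, and Rab37, a small GTPase of vesicle transport, was 2.68 higher on 1 probe and 2.59 on another. The metal ion transporter Slc39a8 (2.44), the water channel Aqp5 (2.36), the p38-type kinase Mapk13 (2.35) and Nxnl2 (2.34) were also among the highest. Mrap2, an accessory protein of melanocortin receptors, was 2.33 higher, and Pou4f1, a transcription factor of sensory neurons, was 2.32 higher. Emilin2, an extracellular matrix protein, had 212 against 42.5 (2.32), and Stac2, a calcium channel adaptor, had 271 against 55.2 (2.29).

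At the low end, Gpr17 (probe at chromosome 18, 32102750 to 32102809) had a scaled signal of 18.7 with valproate and 251 with DMSO, a log2 difference of -3.75. Tmem212 was at -2.63. Deup1, which promotes the formation of centrioles in multiciliated cells, had 31.6 against 178 (-2.49). Tctex1d4 and the transcription factor Foxn4 were both at -2.28, and Glycam1, a secreted mucin, had 67.2 against 317 (-2.24). Fndc9 (-2.18), Spon2 (-1.98), Fam166b (-1.94), Ptx4 (-1.88), Cox8b (-1.85) and Lrrc23 (-1.83) were also among the lowest. Only 3 of these 24 genes had another detected probe, and in all 3 (H2-Ab1, Rab37 and Ptx4) it had the same sign. Among all genes at least 2-fold apart with a second probe, 66 of 69 had the same sign on it, and 43 were also at least 2-fold apart.

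There were 749 genes detected with valproate and not with DMSO, and 160 with DMSO and not with valproate. By their bounds, 109 were at least 2-fold higher and 51 at least 2-fold lower. The DMSO array had the highest detection floor (5.30, against 3.90 for valproate and 4.64 for lamotrigine). Lamotrigine against DMSO was also uneven, with 481 genes detected with lamotrigine alone and 166 with DMSO alone. The highest bounds were those of the protein phosphatase Ppm1j, at least 11.2-fold higher with valproate, the antibody receptor Fcgr3, at least 9.87-fold higher, and the necroptosis kinase Ripk3, at least 8.31-fold higher. The olfactory receptor Olfr714 was at least 5.70-fold lower, Styxl1 at least 5.28-fold and the taste receptor Tas2r126 at least 5.22-fold. Olfr714 and Tas2r126 were detected on the DMSO array alone.

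**Figure D1:**
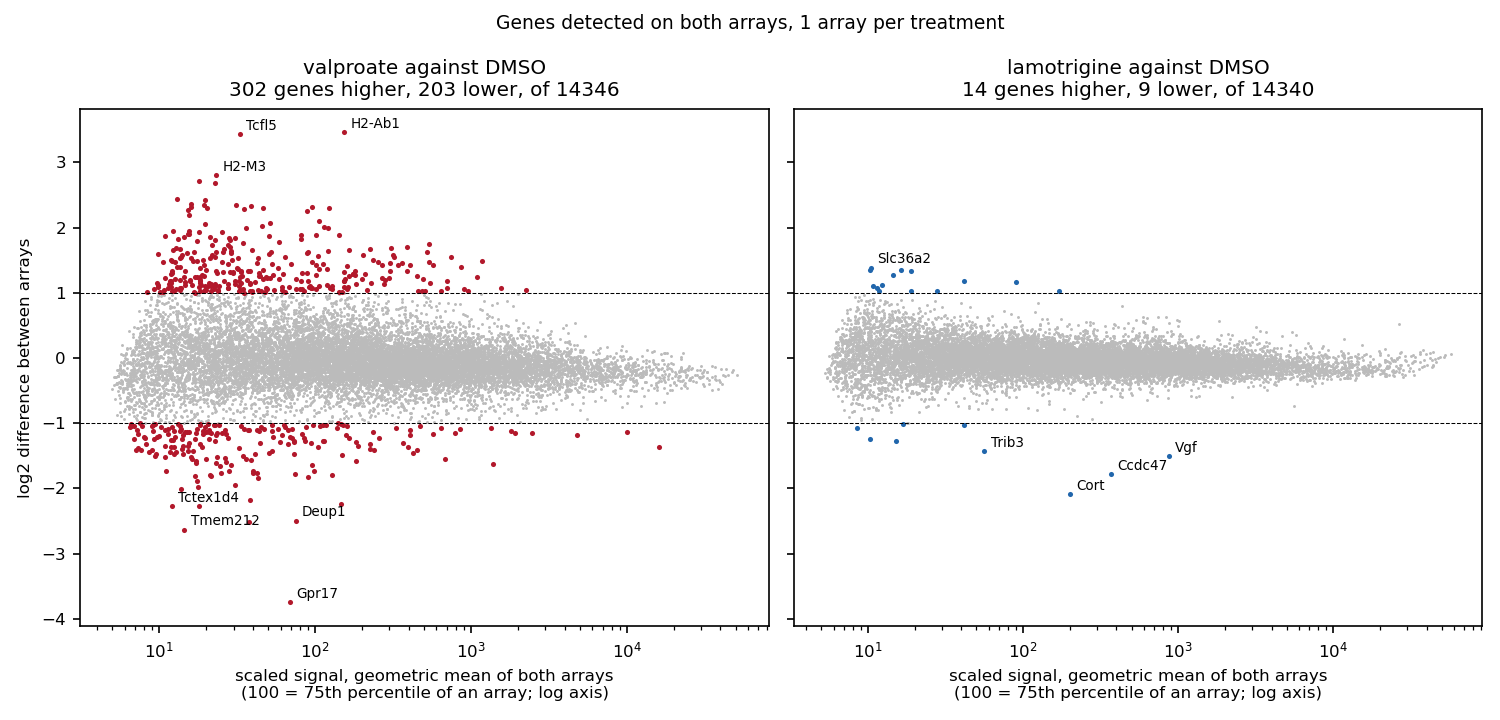
Log2 difference from DMSO of each gene detected on both arrays (vertical axis) against the geometric mean of the scaled signal of the 2 arrays (horizontal log axis), for valproate on the left and lamotrigine on the right, with genes at least 2-fold apart in colour. With valproate 302 genes lay at or above a log2 difference of 1 and 203 at or below -1, against 14 and 9 with lamotrigine.

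Of 20 measured interferon-stimulated genes, 7 were at least 2-fold higher with valproate, 13 lay between and 0 were at least 2-fold lower. Their median of 0.76 was at percentile 100 of the random lists. Bst2, which tethers budding viruses to the cell, was 1.57 higher and Isg15, a ubiquitin-like protein, 1.21. The class I antigen-presenting chains H2-D1 and H2-K1 were 1.55 and 1.24 higher, and their partner B2m was 0.84 higher. Gbp2 (-0.20) and Irf9 (-0.18) were the members below 0, and both lie above 0 with spike-in scaling. Of 18 cytokines and chemokines 8 were measured, and their median of 0.14 was at percentile 87.28 and turns negative without the detection filter. In that list Cxcl12, a chemokine of neuronal migration, was at -1.46, Ccl7 at a bound of -1.19 and Tgfb1 at a bound of 1.67.

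Among 8 measured genes described as raised by HDAC inhibitors, 1 was at least 2-fold higher and 7 lay between, with the median of 0.72 at percentile 99.99. The stress chaperone Hspa1a was 1.54 higher, the growth factor Gdnf 0.96, the linker histone H1f0 0.94 and the actin-severing protein Gsn 0.85. Bdnf (-0.03) and Clu (-0.33) were the members below 0, and both lie above it with spike-in scaling, Bdnf also with the lamotrigine array as control. The HDACs themselves lay within the random range. Of the class I enzymes Hdac1 was at 0.25, Hdac2 at 0.35, Hdac8 at 0.11 and Hdac3 at -0.32, which turns positive with spike-in scaling. The median was 0.18 for class I and -0.08 for the 7 class II and IV enzymes, the latter above 0 with spike-in scaling and with the lamotrigine array as control. Acetyltransferases, DNA methylation enzymes and readers had a median of -0.21 (percentile 2.70), above 0 with spike-in scaling. They lay under the random range with 5 alternatives, at percentiles from 0.52 to 1.835. Of these 5, quantile normalization and the authors' deposited table are nearly the same. The lamotrigine array as control repeats the comparison between the drugs. Among them Kat6b was at -0.70 and Kat5 at -0.60.

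All 19 measured proliferation genes were above 0 with valproate (median 0.46, percentile 100), and 0 were at least 2-fold higher. The replication helicase subunit Mcm2 was 0.78 higher, the nucleotide synthesis enzyme Tyms 0.77 and the cell-cycle marker Mki67 0.52. Cyclin-dependent kinase inhibitors, which slow the cell cycle, had a median of 0.38 over 8 genes (percentile 99.92). Of these 2 were at least 2-fold higher, Cdkn1c at 1.33 and Cdkn2a at 1.09. Wnt target genes had a median of 0.33 over 11 genes (percentile 99.09), with 1 gene at least 2-fold higher. That gene, the transcription factor Lef1, was at 1.05, its relative Tcf7 at 0.94 and Myc at -0.41.

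Every one of the 19 measured cholesterol synthesis genes was below 0 with valproate, with 5 at least 2-fold lower and 14 between (median -0.63, percentile 0). The isomerase Idi1 was at -1.15, Hmgcs1, which makes the precursor of mevalonate, at -1.14 and the sterol sensor partner Insig1 at -1.11. Fatty acid oxidation and PPAR target genes had a median of 0.08 over 20 genes (percentile 98.95), and the mitochondrial carrier Ucp2 was 1.85 higher.

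Of 12 astrocyte markers, 2 were at least 2-fold lower with valproate and 10 lay between (median -0.52, percentile 0). The water channel Aqp4 was at -1.62 and the glycolytic enzyme Aldoc at -1.37, but the filament protein Gfap was at 0.06 and the receptor Fgfr3 at -0.01. With the lamotrigine array as control Gfap lies below 0 and Fgfr3 above, as Fgfr3 does with spike-in scaling. Of 13 measured oligodendrocyte lineage markers, 2 were at least 2-fold lower, Gpr17 and, as a bound, Mag at -1.35 (median -0.38, percentile 0.04). The lineage factor Sox10 was at -0.74, while the myelin genes Ugt8a (0.83) and Mbp (0.60) were higher. All 10 fibroblast and meningeal markers were below 0 (median -0.36, percentile 0.24), with the collagen Col3a1 at -0.97. Neural progenitor and radial glia markers had a median of -0.12 over 11 genes, endothelial and mural cell markers -0.12 over 9, both above 0 with spike-in scaling, and microglia and macrophage markers 0.08 over 7, which turns negative with normexp correction. Flt1, a receptor for vascular growth factor, was at a bound of 2.37.

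Pan-neuronal markers had a median of -0.28 over 15 genes (percentile 1.90) and postsynaptic density and synaptic adhesion genes -0.22 over 26 (percentile 1.57). Both medians turn positive with spike-in scaling. The tubulin Tubb3 was at -0.94, the neurofilament Nefh at -0.93 and the dendritic protein Map2 at -0.64, but the neurofilament Nefm was at 0.60. Excitatory neuron markers had a median of -0.05 over 14 genes, inhibitory neuron markers -0.04 over 14, synaptic vesicle and release genes -0.12 over 28 and metabotropic receptors -0.17 over 9. Genes of GABA synthesis, transport and breakdown had a median of -0.28 over 9 (percentile 5) and voltage-gated sodium channels -0.07 over 10. All 6 of these lists lay within the random range and turn positive with spike-in scaling, the excitatory and inhibitory ones also with quantile normalization and the inhibitory, vesicle and metabotropic ones also with the lamotrigine array as control. The GABA synthesis list lay under the random range with quantile normalization (percentile 2.345) and with the authors' deposited table (2.405), itself quantile-normalized. Ionotropic glutamate receptors (0.02 over 17 genes), potassium channels (0.02 over 25), calcium channels (0.02 over 17) and GABA-A receptor subunits (0.08 over 13) also lay within it, the glutamate receptor and potassium channel medians turning negative with normexp correction. Single members stood apart, such as the GABA-A subunit Gabrd, 1.28 higher, the calcium channel subunit Cacna2d2 at 0.87 and Gabrg1 at 0.77.

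Neuropeptides and granins had a median of 0.11 over 22 genes (percentile 99.45), with galanin (Gal) at 0.94, Trh at 0.85 and Penk at 0.64. Neurotrophic factors and receptors had members in both directions around a median of 0.05 over 17 genes. The receptor Ret was 1.53 higher, and neurturin (Nrtn) 1.16 higher, and Ntf5 had a bound of more than 2-fold, while Cntf was at -1.23 and Fgf1 at -1.09. Immediate early genes had a median of 0.05 over 17, which turns negative with normexp correction, without the detection filter and with the lamotrigine array as control. The activity-dependent factor Npas4 had 32.3 with valproate and 68.9 with DMSO, and Egr1 was 0.69 higher. Apoptosis genes had a median of -0.01 over 18, with Pmaip1 at 1.23. Heat shock proteins had a median of -0.16 over 14, with Hspb1 at 1.06 and Hspb8 at -0.80. Endoplasmic reticulum and integrated stress genes had a median of -0.17 over 16, with Sdf2l1 at 0.97, Trib3 at -1.28 and Chac1 at -0.84, of which Trib3 (0.15) and Chac1 (0.10) lie above 0 with the lamotrigine array as control. The last 3 medians turn positive with spike-in scaling, those of the apoptosis genes and heat shock proteins also with the lamotrigine array as control, and that of the apoptosis genes also with quantile normalization and normexp correction. Reference genes had a median of -0.21 over 12, and Gapdh was at -0.27, both above 0 with spike-in scaling, quantile normalization and the authors' deposited table. Actb (-0.48) and Polr2a (-0.58) stay below 0 under these, and Hprt was at 0.28.

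The 302 higher and 203 lower genes became 111 and 80 with normexp background correction, 864 and 1095 without the detection filter and 707 and 79 with spike-in scaling. This scaling adds 0.33 to the difference of each gene detected on both arrays and was chosen after the data were seen. Of 36 lists, 13 lay outside the random range, against 1.8 if genes and lists were independent, which members regulated or listed together are not, and 8 stayed outside under every alternative; the Wnt, fatty acid, neuropeptide, pan-neuronal and postsynaptic lists did not.

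**Figure D2:**
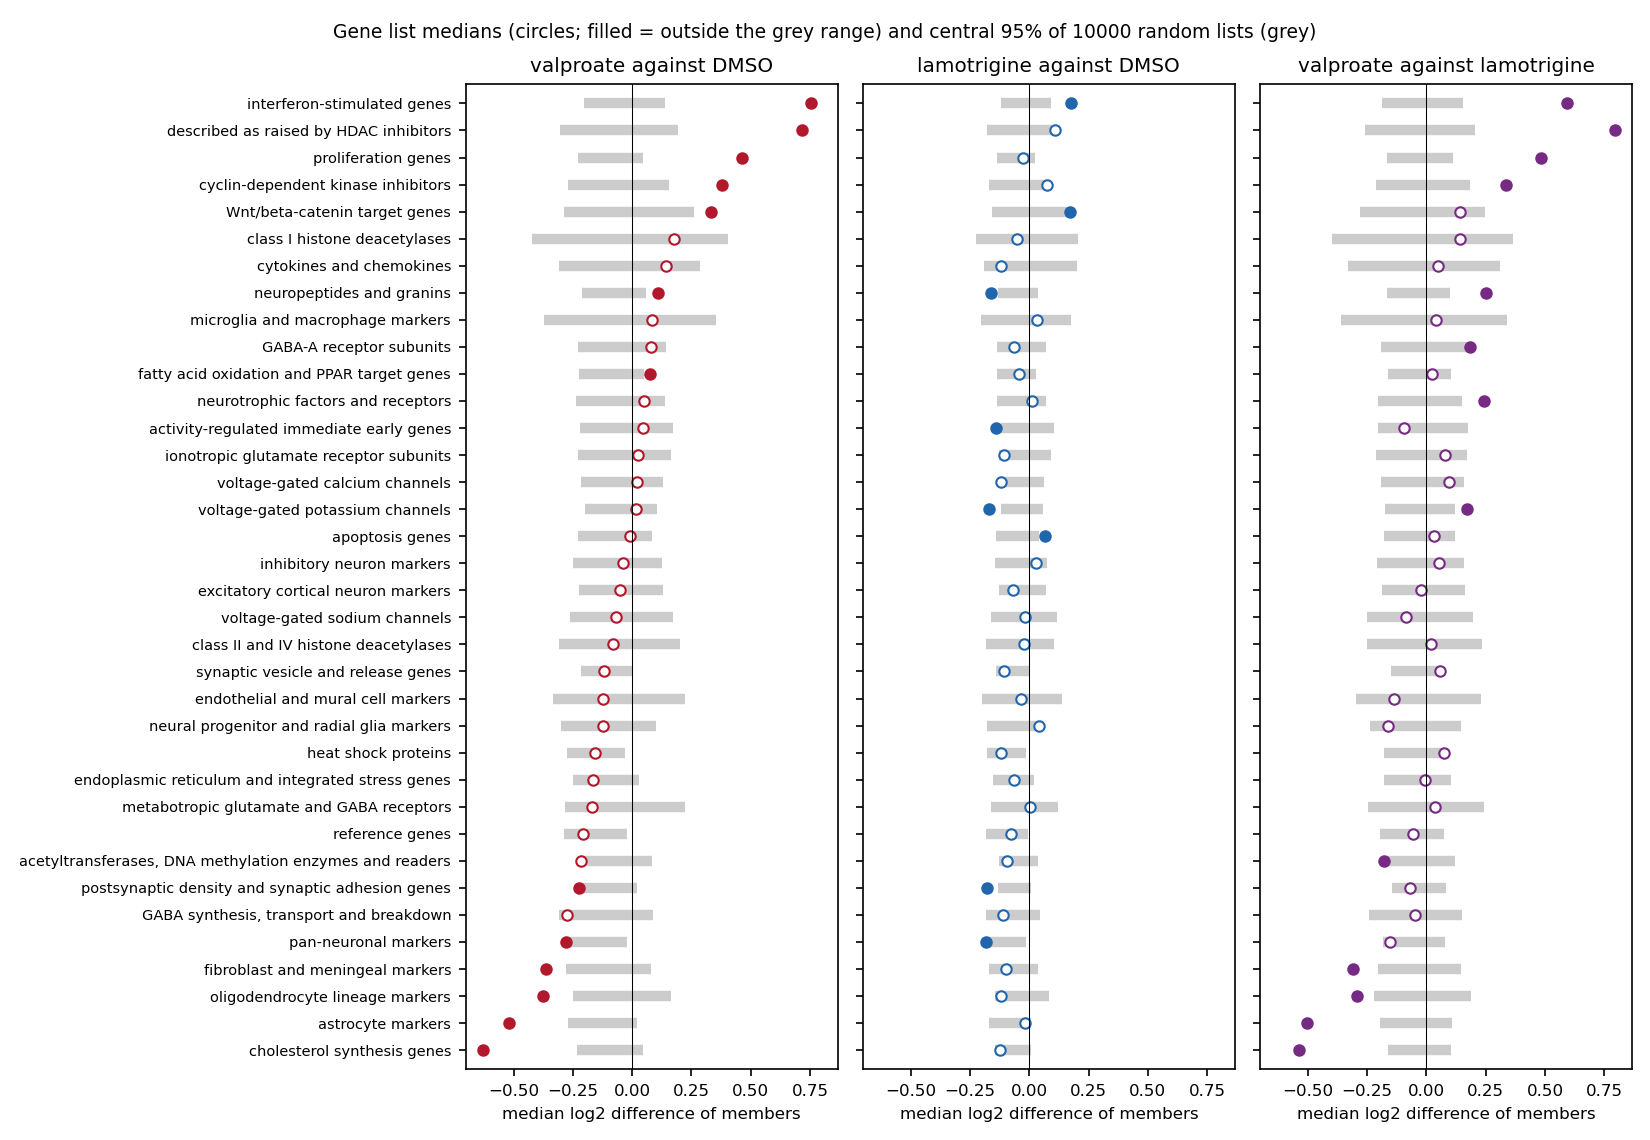
Median log2 difference of each gene list (points) in the 3 comparisons, with the central 95% of medians of 10000 random lists matched on level as bars. For valproate against DMSO the interferon-stimulated genes lie at 0.76 and the cholesterol synthesis genes at -0.63.

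**Figure D3:**
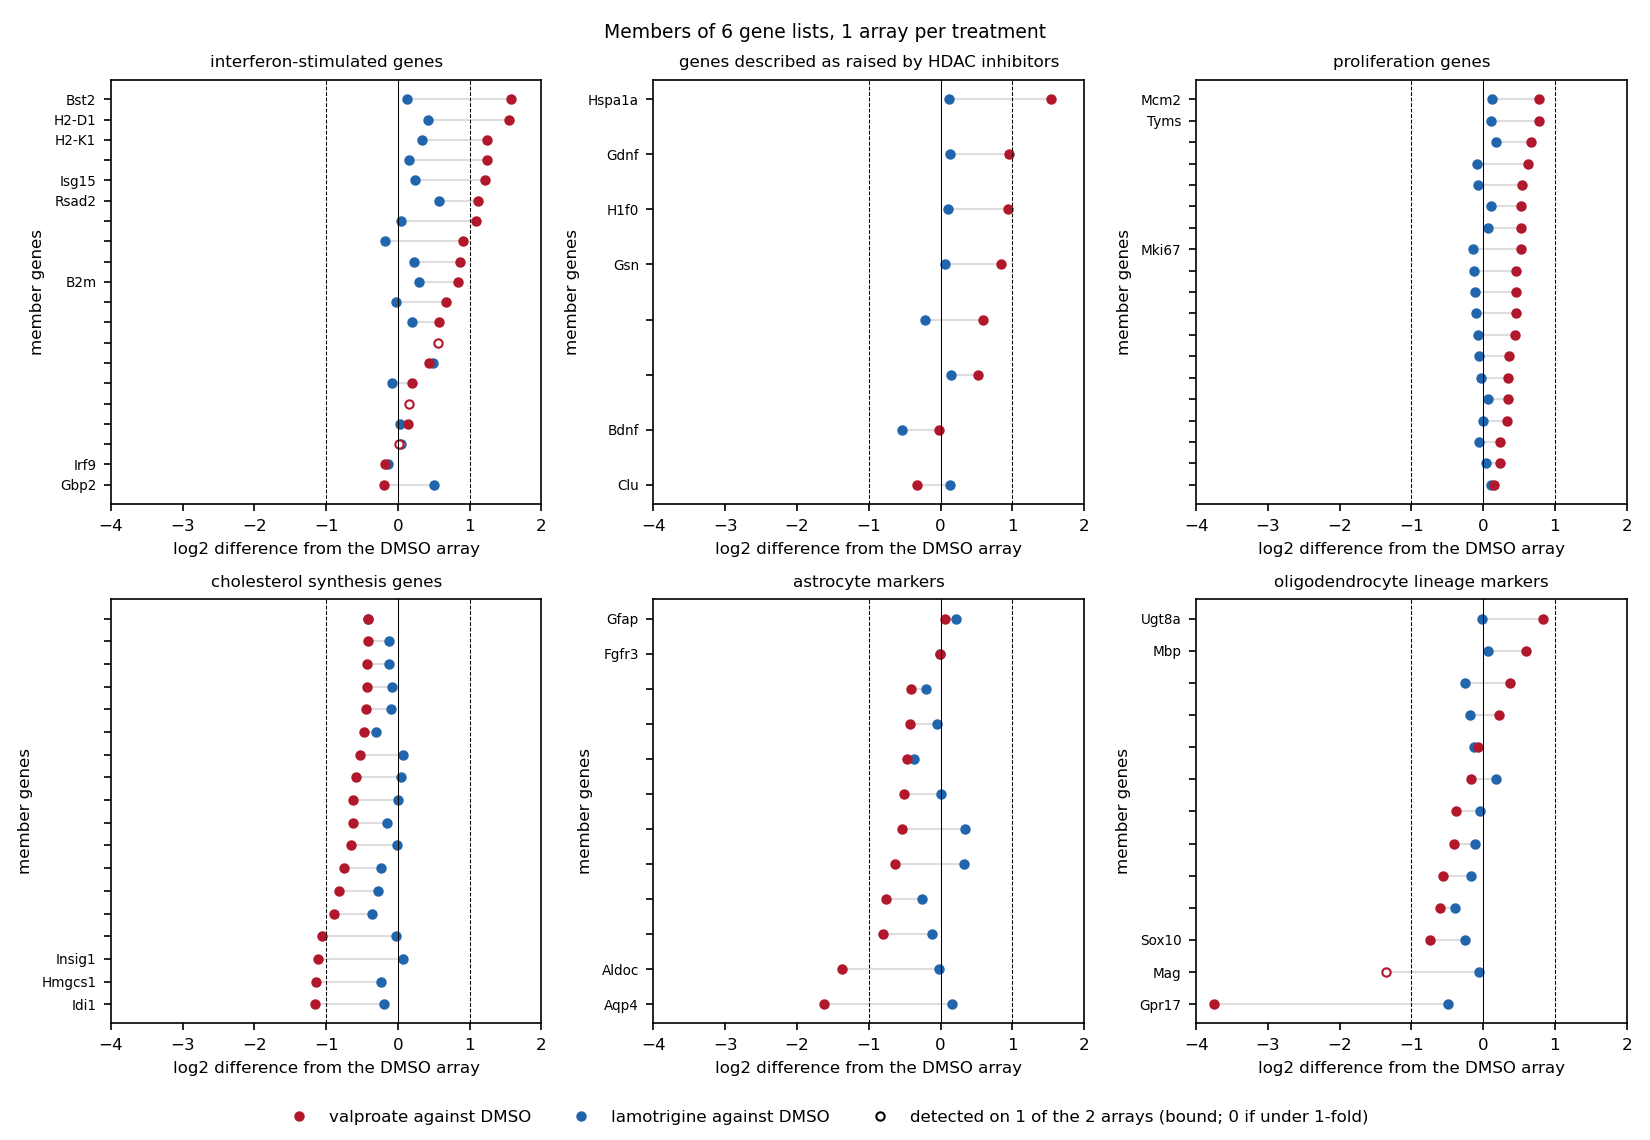
Log2 difference of each member (points) of selected gene lists for valproate and lamotrigine against DMSO, with 1 array per treatment. The 18 cholesterol synthesis genes drawn, of 19 measured, lie below 0 with valproate, and astrocyte markers reach from -1.62 for Aqp4 to 0.06 for Gfap.

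Lamotrigine was set against DMSO as a second drug on the same slide; the labels place this array outside the HDAC inhibitor study, in work on antiepileptic drugs. Far fewer genes stood apart with lamotrigine than with valproate, 14 at least 2-fold higher and 9 at least 2-fold lower of 14340 detected on both arrays, and the SD of the differences was 0.21 against 0.42. Among the lowest genes were cortistatin (Cort), a peptide of inhibitory neurons, 4.26-fold lower, and Vgf, a secreted granin, 2.83-fold lower. Interferon-stimulated genes had a median of 0.18 (percentile 99.91), and the voltage-gated sodium channels, the drug's known targets, had a median of -0.02 over 11 genes, which turns positive with spike-in scaling.

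Cort had a scaled signal of 97.7 with lamotrigine and 416 with DMSO, a log2 difference of -2.09. Vgf (probe at chromosome 5, 137509153 to 137509212 on mm9) had 517 with lamotrigine and 1465 with DMSO. Ccdc47 was at -1.78, but its 2 other probes were at -0.08 and 0.09. Trib3, a pseudokinase of the integrated stress response, was at -1.43, the homeobox gene Rhox5 at -1.27, the secreted protein Spp1 at -1.24, the potassium channel Kcnj3 at -1.07 (its other probe at -0.23) and the lipid kinase Dgkg at -1.02. The amino acid transporter Slc36a2 was the highest, 2.61-fold higher at a scaled signal of 16.8 against 6.43. Bhlha9 and Rps6kc1 were 1.34 higher, Fam47e 1.28, Slc4a9 1.19, the matrix protein Npnt 1.12, Sh3rf2 1.11 and Scara5 1.07. The other probe of Npnt was at 0.25, and the gene was at -0.015 with normexp correction. Of 3 genes at least 2-fold apart with a second probe, 3 had the same sign on it and 0 were also at least 2-fold apart.

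Several neuronal lists had medians under the random range with lamotrigine. Postsynaptic density and synaptic adhesion genes were at -0.18 over 26 genes (percentile 0.01) and pan-neuronal markers at -0.18 over 15 (percentile 1.425). Both also lay under it with valproate against DMSO (percentiles 1.57 and 1.90), and within it between the drugs (24.1 and 6.455). For them, an unusual DMSO array and a difference common to both drugs cannot be told apart. Voltage-gated potassium channels were at -0.17 over 25 (percentile 0.08), neuropeptides and granins at -0.16 over 22 (percentile 0.36) and immediate early genes at -0.14 over 17 (percentile 1.15), and these 3 medians turn positive with spike-in scaling. With valproate against DMSO these 3 lists did not lie under the random range. Among their members Cartpt was at -0.83, Egr4 at -0.79, Arc, a synaptic immediate early gene, at -0.68 and Kcna1 at -0.46. Ier2 lay the other way at 0.56. Of the members of all 5 lists only Vgf was at least 2-fold lower.

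Above the random range lay interferon-stimulated genes with 18 measured members, 0 of them at least 2-fold higher, Wnt target genes (0.17 over 11, percentile 97.84) and apoptosis genes (0.07 over 17, percentile 99.29). Rsad2, an antiviral enzyme, was 0.58 higher, Gbp2 0.51, Tcf7 0.43 and Hrk, which promotes neuronal death, 0.63. The Wnt list also lay above the random range with valproate against DMSO (percentile 99.09) and within it between the drugs (90.55). For this list too, an unusual DMSO array and a difference common to both drugs cannot be told apart. In the integrated stress list, with a median of -0.06 over 16 genes that turns positive with spike-in scaling and quantile normalization, Chac1 was at -0.94, Asns at -0.44 and Atf4 at -0.43. With valproate against DMSO, Chac1 was at -0.84, Asns at -0.17, Atf4 at -0.60 and Trib3 at -1.28. Between the drugs these genes were at 0.10, 0.27, -0.18 and 0.15. The lists far from 0 with valproate were nearer to it with lamotrigine against DMSO, with medians of -0.12 for cholesterol synthesis genes, -0.02 for astrocyte markers, -0.12 for oligodendrocyte lineage markers and -0.02 for proliferation genes, all above 0 with spike-in scaling and the astrocyte and proliferation medians also with quantile normalization. The oligodendrocyte list nevertheless lay under the random range with 5 alternatives, at percentiles from 0.74 to 1.85. The cholesterol list did so with quantile normalization (1.32) and the authors' deposited table (1.26). For both lists, quantile normalization and the deposited table are nearly the same alternative. Genes described as raised by HDAC inhibitors had a median of 0.11.

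Of the 23 genes, 10 of the higher and 4 of the lower ones had a scaled signal under 25, where the technical SD is largest. The count became 4, all lower, with normexp correction. Spike-in scaling, which adds 0.17 to the difference of each gene detected on both arrays, made it 43. The balance turned to 11 higher and 15 lower with quantile normalization and with the authors' deposited table. The immediate early, postsynaptic, potassium channel and Wnt lists did not stay outside the random range under every alternative.

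Valproate was set against lamotrigine because this comparison leaves out the DMSO array. Interferon-stimulated genes had a median of 0.59, with 5 at least 2-fold higher, genes described as raised by HDAC inhibitors 0.80 and proliferation genes 0.48, each at percentile 100. Cholesterol synthesis genes were at -0.54 and astrocyte markers at -0.51, both at percentile 0. Of 14544 genes detected on both arrays, 300 were at least 2-fold higher and 246 at least 2-fold lower with valproate.

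Among genes detected on both arrays H2-Ab1 was the highest at 3.31, followed by Tcfl5 at 2.92, Stac2 at 2.79, Rab37 at 2.77 and the lactate transporter Slc16a3 at 2.76. Gpr17 was the lowest of them at -3.25, and Tmem212 at -2.69, Deup1 at -2.65, Tctex1d4 at -2.40 and Foxn4 at -2.29 were the next that are not clones. Of 494 genes at least 2-fold apart between valproate and DMSO and detected on all 3 arrays, 340 (68.8%) were also at least 2-fold apart from lamotrigine in the same direction. A second probe had the same sign for 89 of 93 genes.

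Neuropeptides and granins were 0.25 higher with valproate than with lamotrigine at the median of 22 genes (percentile 100), with Vgf at 1.77, Cartpt at 1.30 and Gal at 1.14 at least 2-fold higher. Neurotrophic factors and receptors (0.24, percentile 99.74), cyclin-dependent kinase inhibitors (0.33, percentile 99.82), potassium channels (0.17, percentile 99.6) and GABA-A receptor subunits (0.19, percentile 97.67) also lay above the random range. Oligodendrocyte lineage markers (-0.29, percentile 0.34), fibroblast and meningeal markers (-0.31, percentile 0.06) and acetyltransferases, DNA methylation enzymes and readers (-0.18, percentile 1.81) lay under it. The potassium channel, GABA-A, oligodendrocyte and acetyltransferase lists lay within the random range under at least 1 alternative. The 300 higher and 246 lower genes became 126 and 95 with normexp correction, 455 and 161 with spike-in scaling and 784 and 1251 without the detection filter.

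Across 14249 genes detected on all 3 arrays, the valproate and lamotrigine differences from DMSO had a Pearson r of 0.263, a Spearman rho of 0.302 and a covariance of 0.0235. Both differences use the DMSO array, and genes are not independent replicates. Simulated unchanged arrays that share 1 control gave an r of 0.500 and, at the technical spread between spots, a covariance of 0.00376. This r follows from equal noise on each array, whereas the valproate and lamotrigine differences had variances of 0.175 and 0.0455. The simulated covariance leaves out differences of the DMSO culture, RNA and labelling. Neither value therefore tells how much of the correlation comes from the shared array. Genes at least 2-fold higher with both drugs numbered 3 (C1s1, Gm9732 and Npnt, the last not with normexp correction), and 1 gene (Trib3) was at least 2-fold lower with both. Independent lists would share 0.288 and 0.127 genes, but these lists share the DMSO array, and the overlap of unchanged arrays with a shared control was not simulated. C1s1, a complement protease, and Gm9732 were named because the count was small.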

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

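Scaling on the spike-in controls was chosen only after the results were seen, and the other alternatives were planned. No paired analysis was possible because there was 1 array per treatment. Centring on detected probes, detection on all 3 arrays and kept outlier spots left every count of genes at least 2-fold apart within 1.5 times its value and the correlation near 0.263. Thresholds act by construction. At 1.5-fold, valproate against DMSO had 1750 genes (900 higher, 850 lower), lamotrigine against DMSO 269 (161 and 108) and valproate against lamotrigine 1748 (898 and 850). At 3-fold these were 109 (75 and 34), 2 (0 and 2) and 119 (77 and 42). Normexp correction, whose offset shrinks differences of dim spots, gave 191 (111 and 80), 4 (0 and 4) and 221 (126 and 95), and put Npnt at -0.015 for lamotrigine against DMSO. Without the detection filter, which adds undetected genes, the counts were 1959 (864 and 1095), 1163 (636 and 527) and 2035 (784 and 1251), with 44.1% and 38.5% of the valproate genes higher in place of 59.8% and 54.9%, and the correlation was 0.375. Quantile normalization and the authors' deposited table each gave 15 lower and 11 higher genes for lamotrigine against DMSO, and the mean of detected probes gave 22 higher ones; the cause was not tested. Spike-in scaling moved the median of all genes from -0.08 to 0.25 for valproate against DMSO, from -0.04 to 0.13 for lamotrigine against DMSO and from -0.03 to 0.13 between the drugs. The counts became 786 (707 and 79), 43 (37 and 6) and 616 (455 and 161), and 381 of the 505 genes apart between valproate and DMSO were still apart in the same direction. This shift, uniform for genes detected on both arrays, also turned list medians positive. They became 0.106 for postsynaptic genes and 0.051 for pan-neuronal markers with valproate. With lamotrigine they became 0.004 for potassium channels, 0.034 for immediate early genes and 0.011 for neuropeptides. Bounds set to 0 do not move with it, so percentiles can change, but no list outside the random range moved inside. With the lamotrigine array as control, Trib3 was at 0.146 with valproate; the cause was not tested. Of the 505 genes, 484 were still apart in the same direction under quantile normalization, 188 under normexp and 484 with the mean of probes. Lists outside the random range under every alternative numbered 8 of 13, 4 of 8 and 9 of 13. For valproate against DMSO, 4 of the others left it with the lamotrigine array as control, at percentiles of 90.55 (Wnt), 79.6 (fatty acid), 24.1 (postsynaptic) and 6.455 (pan-neuronal), and neuropeptides with normexp (97.32). The postsynaptic list also left it with the mean of detected probes, and the pan-neuronal list also with normexp. For lamotrigine against DMSO, the Wnt list reached 95.97, immediate early genes 6.27, postsynaptic genes 11.36 and potassium channels 2.655. Between the drugs, GABA-A subunits reached 93.3, potassium channels 92.04, acetyltransferases 3.03 and oligodendrocyte markers 2.89. Lists inside the random range also left it. For valproate against DMSO, acetyltransferases did so with 5 alternatives (percentiles from 0.52 to 1.835), GABA synthesis with quantile normalization (2.345) and the deposited table (2.405), and GABA-A subunits (97.67), potassium channels (99.6) and neurotrophic factors (99.74) with the lamotrigine array as control. For lamotrigine against DMSO, oligodendrocyte markers did so with 5 alternatives (0.74 to 1.85), cholesterol genes (1.32 and 1.26) and calcium channels (0.49 and 0.47) with quantile normalization and the deposited table, and progenitor markers without the filter (99.31) and with the mean of probes (99.83). Between the drugs, Wnt targets did so with normexp (97.52) and the mean of probes (99.23), and heat shock proteins without the filter (97.65). Quantile normalization and the deposited table are nearly the same alternative, since that table is quantile-normalized. The lamotrigine array as control repeats the comparison between the drugs. Dim signal limits the single genes, since the SD of the valproate differences was 0.60 at a scaled signal under 25 and 0.28 over 400.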

Other observations

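Of the tests given here, only those of spot noise and of the astrocyte share were planned before their results were seen; all other tests, the motile cilium list and the genes singled out in the next paragraph were chosen after.

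Values of single antigen presentation genes outside the lists differed in direction between valproate and DMSO, and no list of them was tested. The class I genes H2-T23, H2-Q2 and H2-Q7 had log2 differences of 1.70, 1.63 and 1.43, the immunoproteasome subunit Psmb9 1.44 and the peptide transporter Tap1 1.30. Probes of class I genes can bind related transcripts, so these values are not independent. The class I activator Nlrc5 was at 0.69. H2-Eb1, a chain of another class II molecule than that of H2-Ab1, was at -0.25. The invariant chain Cd74, dim on both arrays, was at -0.01, and both turn positive with spike-in scaling.

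Among probes for long intergenic RNA regions, 46 were at least 2-fold higher and 60 lower with valproate than with DMSO of 3964 detected on both arrays, against 9 and 7 of 3940 with lamotrigine. Valproate against lamotrigine had 52 and 59 of 4180. Other probes without a gene had 22 higher and 34 lower with valproate, 7 and 3 with lamotrigine, and 20 and 38 between the drugs.

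The 505 genes at least 2-fold apart between valproate and DMSO could stem from spot noise, from an unusual DMSO array or from the single valproate sample. Spot noise is argued against for the 69 of them with a second probe, since 95.7% had the same sign on it. Among all genes with a second probe the share was 73.8%. The rest of the 505 had no such check, and 114 higher and 99 lower genes had a scaled signal under 25. The DMSO array alone is argued against too, since 68.8% of the 494 detected on all 3 arrays were also at least 2-fold apart from lamotrigine in the same direction. A difference in culture, RNA or labelling of the valproate sample other than the drug cannot be told apart from the drug, because the number of valproate samples is 1. Part of the correlation between the drugs' differences may likewise come from the shared DMSO array. The simulated r of 0.500 cannot tell how much, because it follows from equal noise on each array.

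The interferon-stimulated genes, with a median of 0.76, could be higher because the valproate culture held more immune or vascular cells. The 75th percentile of the measured microglia and macrophage markers was 0.294, 0 of the 6 detected on both arrays reached that median, and the abundant microglial genes C1qa, Tyrobp, Ctss and Laptm5 were detected on no array, although Fcgr3 had a bound of 3.30. The 75th percentile of endothelial and mural cell markers was 0.237, and 0.371 with markers known only as lower bounds set highest. Of the 9 measured, 1 reached the median of the interferon-stimulated genes, Flt1 at a bound of 2.37. Of the 7 detected on both arrays 0 did, a count that leaves out markers gained with valproate. Both lists argue against more of these cells as the source of the whole group. An effect of the drug and another difference of the single valproate culture stay open. The median was 0.18 with lamotrigine against DMSO and 0.59 between the drugs. Part of the 0.76 may therefore come from the DMSO array or from a difference common to both drugs.

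Astrocyte markers, with a median of -0.52, could be lower because of the array's scaling or a smaller share of astrocytes. Scaling is argued against, since the astrocyte median lay -0.312 from that of the reference genes, which any common factor leaves as it is. A smaller share was predicted to lower all markers alike, within 2 technical SDs of their median. Of 12 markers, 2 lay above their median by more than that (Gfap and Fgfr3) and 4 below, so this prediction was not met. The 2 above were also short of the 25% set in advance as evidence against a smaller share. The technical SD leaves out differences between cultures, RNA extractions and labelling reactions. Valproate differences over all genes had an SD of 0.42. Markers could thus miss the predicted range under either explanation, so the miss does not decide between them. A smaller share of astrocytes and a lower expression per astrocyte therefore cannot be told apart.

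A further hypothesis is that valproate lowered genes of motile cilia, prompted by Deup1 and Foxn4 among the lowest genes. On 37 measured genes of a list written without the genes named before, the median was -0.466 (percentile 0), with 7 at least 2-fold lower and 0 higher. Against lamotrigine it was -0.63 (percentile 0), and for lamotrigine against DMSO 0.11 (percentile 99.85). The same valproate array prompted the hypothesis, and genes regulated together are not independent as the random lists assume. The percentiles with valproate are therefore no independent support for it. Cfap126 was at -1.42, the dynein Dnah6 at -1.30 and Ccno, which drives multiciliated cell formation, at -1.28, while Mcidas was at 0.13. The master regulator Foxj1 was at -0.67. The values are consistent with lower cilium gene expression or with fewer ciliated cells, and the single valproate culture leaves other causes open.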
